A study of Mus musculus with 2 samples.

How the data were processed

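The series compared 2 libraries of cells from subcutaneous fibrosarcomas in C57BL/6 mice, 1 per group. Per the labels' protocols, tumours were minced, digested with collagenase B and DNase I at 37 °C for 45 minutes, filtered and freed of erythrocytes by lysis, and libraries were made with the 10x Genomics single-cell 3' v3 chemistry, which reads the end of each transcript and counts molecules by unique molecular identifiers (UMIs). The deposited values were raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.1.0 on mm10 per the submitters' processing notes, and per the file headers the same software version wrote the count matrices. The annotation release, the setting used to call barcodes, any cell sort and the number of animals per library are not given in the sources used here. Droplets below the calling limit were not used here, so free RNA was read from the transcripts of other cell classes. Because reads fall at the transcript end, near-identical family members, such as the MHC class I, granzyme and mast cell protease genes, can share or lose reads, and their single values are uncertain.

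Libraries were grouped by their titles. Their treatment labels contradict the titles, and the values were not used to decide between them. Of 31053 gene identifiers 30934 were found in GENCODE M21 (GRCm38), which was used for coordinates only.

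Cells with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 8985 of 9475 barcodes titled Control and 11617 of 12057 titled Blood. Doublets were called per library with Scrublet (scanpy 1.11.5) at an expected rate of 0.8% per 1000 barcodes and removed. The automatic threshold marked 157 cells (1.75%) and 278 cells (2.39%), against expected rates of 7.19% and 9.29%, so doublets remain among the kept cells. Counts were scaled per cell, log-transformed and reduced to 2000 variable genes and 30 components without batch integration. Cells of both libraries were clustered together on a graph of 15 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), and clusters whose best 2 lineages scored alike were split once more at resolution 0.5.

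Clusters were named from 21 marker lists. A name needed a mean standardised marker score of at least 0.5, a margin of 0.35 over the next lineage and at least 3 markers detected in 5% of cells. Its markers also could not be outnumbered by those of another class among its top 10 genes by fold. Low-UMI clusters, with a median under 1/3 of that of all kept cells, were named only if an own marker was among their top 10 genes against all other cells. These score limits were set after the data were seen. The clusters left unnamed held 3.73% of the library titled Control and 1.76% of the library titled Blood where NK and T cell markers scored alike, 2.89% and 2.70% in a pair of low-UMI clusters, with stromal and with macrophage markers, that had 0 own markers among those 10 genes, although 4 and 5 were there against cells outside the class, and 1.07% and 0.750% in a cluster of low score led by Ctsk and Acp5.

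Raw counts were summed per library and class and given as CPM, UMI counts scaled to a common class total, with exact Poisson intervals, shares with exact Clopper-Pearson intervals, and ratios with exact conditional binomial intervals, all at 95% and covering counting error only. Log2 ratios were taken of CPM plus a pseudocount of 5, which draws low genes towards 0. No p-value, standard error or count of changed genes was made from cells. The class sums were 87212184 and 84562739 UMIs for macrophage-like, 4710794 and 6743833 for T cell-like, 281436 and 3204036 for neutrophil-like, 2231196 and 3265969 for monocyte-like, 2474070 and 2309120 for NK cell-like, 2839400 and 2521486 for conventional DC-like and 5635161 and 3398110 for mesenchymal-like cells. Where no UMI was found, the limit given is that of 3 counts.

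For gene lists, the median log2 ratio was taken over members with at least 10 CPM in either library and at least 10 counts. Its percentile was found among 10000 random lists of the same size matched over 20 bins of expression, as a description of these libraries. Lists with under 5 measured members in a class gave no median. The fixed rule for named genes took, in macrophage-like cells, the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 50 CPM in either library and at least 100 counts, 8 and 8 in mesenchymal-like cells and 4 and 4 in other classes with at least 100 cells in both libraries. It left out mitochondrial, ribosomal, predicted, globin, immunoglobulin, T cell receptor, Xist and Y-linked genes, and added a set of haem, iron and oxidative stress genes and up to 3 members per list. Bnip3, Ero1l, Mif and Ldha in neutrophil-like cells and Gzmf and Gzmb in NK cell-like cells were chosen after their values were seen. The mesenchymal-like class was planned as a comparison whatever its size.

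The ratios, intervals and list percentiles were run on simulated class sums with 200 genes changed by known folds. The counts were drawn with Poisson error only, the error that the intervals assume, so coverage near 95% was built in. Variation between cells, clusters, animals or libraries was not simulated, and filtering, doublet calling, clustering and naming were not run. In the simulated macrophage-like comparison, run on 2944 genes, the intervals covered the true ratio for 95.0% of genes, 100% of 3-fold changes were found and 0% of unchanged genes passed 1.5-fold. In the simulated neutrophil-like comparison, run on 2519 genes, coverage was 94.9% and 4.04% of unchanged genes passed 1.5-fold.

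The comparisons, lists, markers, named-gene rule and 13 alternative settings were fixed before the data were examined. A further 4 settings and all but 1 of the tests of explanations were added after seeing the data. The alternatives covered the cell filters, doublets, clustering, depth, scaling, pseudocount, low-value filter and denominator of shares. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, anndata 0.12.19 and matplotlib 3.10.9.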

Results

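Cells of subcutaneous fibrosarcomas, connective tissue tumours grown from implanted syngeneic cells in C57BL/6 mice, were profiled by droplet-based single-cell RNA sequencing. The study set tumours injected with the animals' own erythrocytes in buffered saline against tumours injected with saline, so the comparison addresses how blood cells placed in a tumour bear on the cells found there. There was 1 library per group. The labels of the libraries contradict each other: the library titled Control carries the treatment of erythrocyte injection, and the library titled Blood carries the treatment of saline injection. The libraries are therefore named by their titles, every difference is given as titled Blood against titled Control, and no direction can be read as an effect of erythrocytes. With 1 library per group no test was possible and no difference has a replicate check. All intervals are exact 95% intervals covering counting error only, and the differences describe these libraries, not the conditions.

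The library titled Control held 9475 barcodes and 115272096 UMIs, and the library titled Blood 12057 barcodes and 115066023 UMIs. After filtering, 8828 and 11339 cells were kept, with a median of 9246 and 6566 UMIs and 2742 and 2205 genes per cell. Within classes the median UMIs were closer, at 12692 and 11503 in macrophage-like and 6710 and 6828 in monocyte-like cells. The median mitochondrial share was 3.45% and 3.03%. Xist, the RNA of the inactive X chromosome, stood at 731 and 752 CPM (UMI counts scaled to a common total) over all kept cells, and the Y-linked Ddx3y had no UMI in either library, which allows up to 0.0269 and 0.0272 CPM. Hbb-bs, an adult haemoglobin chain, was at 0.108 CPM (0.0556 to 0.188) and 0.535 CPM (0.407 to 0.690). Erythrocytes were lysed during preparation, so the globin values do not show which tumour had received them.

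Macrophage-like cells made up most of both libraries, and neutrophil-like cells stood apart most between them. Neutrophil-like cells, marked by the calgranulins S100a8 and S100a9, were 1.52% of kept cells (1.27% to 1.80%, 134 cells) in the library titled Control and 15.7% (15.01% to 16.4%, 1777 cells) in the library titled Blood, a ratio of 10.3 (8.66 to 12.4). Macrophage-like cells, marked by complement C1q and Csf1r, were 68.0% (67.1% to 69.0%) and 56.5% (55.6% to 57.4%). T cell-like cells were 9.41% (8.81% to 10.0%) and 11.3% (10.75% to 11.9%), and NK cell-like cells 4.43% (4.01% to 4.88%) and 3.62% (3.28% to 3.98%). Conventional DC-like cells, the antigen-presenting dendritic cells, were 2.67% (2.35% to 3.03%) and 1.85% (1.61% to 2.12%).

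Mesenchymal-like cells, the class that would hold both tumour cells and fibroblasts, were few, at 1.17% (0.953% to 1.41%, 103 cells) and 0.467% (0.3503% to 0.611%, 53 cells). A further cluster with stromal markers and a low UMI count was left unnamed, and counting it brought the class to 2.92% and 1.90%, a ratio of 0.649 in place of 0.401. Monocyte-like cells were 3.70% (3.32% to 4.12%) and 4.28% (3.91% to 4.67%), but this order turned when each library was clustered on its own, with a ratio of 0.733. Migratory DC-like cells were 0.702% and 0.529%, B cell-like cells 0.408% and 0.538%, and plasmacytoid DC-like cells 0.261% (23 cells) and 0.0353% (4 cells). Unnamed clusters held 7.68% and 5.20%. Neutrophil-like cells had a median of 1970 and 1746 UMIs, far under other classes, and neither a cell sort nor the setting used to call barcodes is given in the sources used here, so shares can move with depth and with the calling of low-UMI barcodes; among cells with at least 5000 UMIs the neutrophil-like ratio was 4.28 (1.18 to 23.4).

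**Figure D1:**
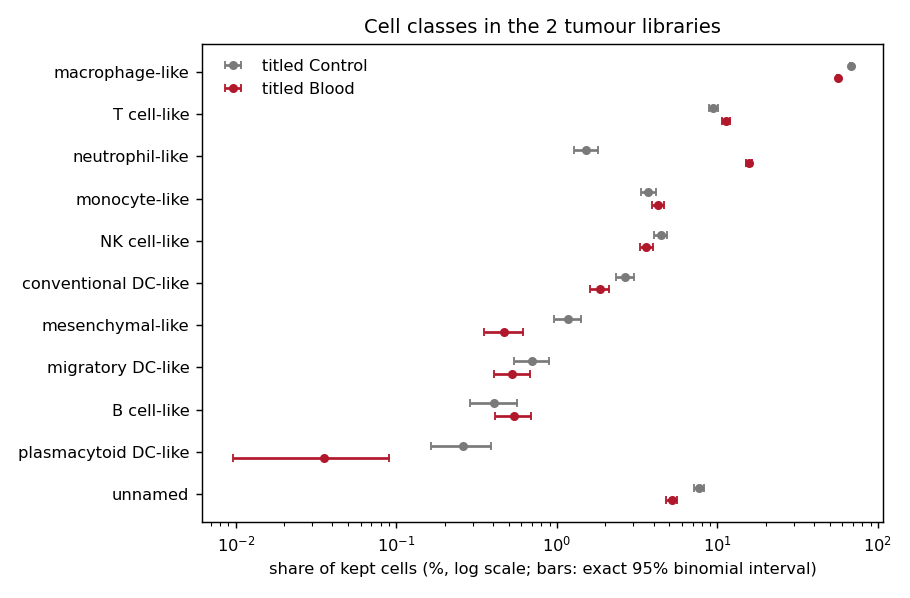
Share of kept cells in each cell class (x axis, percent, log scale) for the libraries titled Control (grey) and titled Blood (red), 1 library each, with bars for exact 95% binomial intervals. Neutrophil-like cells sit at 1.52% and 15.7%, and macrophage-like cells at 68.0% and 56.5%.

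In macrophage-like cells, genes induced by interferon were lower in the library titled Blood. Of 22 measured interferon-stimulated genes, 17 were at least 1.5-fold lower and 0 at least 1.5-fold higher, and the median log2 ratio was -0.87. That median lay below all of 10000 random lists matched on expression, whose central 95% ran from -0.05 to 0.06. Irf7, the transcription factor that amplifies the type I interferon response, was at 264 CPM (261 to 267.5) and 117 CPM (114.5 to 119), a ratio of 0.442 (0.432 to 0.453). The antiviral genes Isg15 (326 and 158 CPM), Ifit3 (89.9 and 33.3 CPM), Ifit2 (76.2 and 33.2 CPM) and Oasl1 (62.1 and 28.7 CPM) were lower as well. The list for interferon gamma and MHC class II had a median of -0.22, with 0 of 20 members past 1.5-fold in either direction; H2-Eb1, an MHC class II chain, was at 3085 and 2175 CPM. The MHC class I presentation list had a median of -0.19, with 0 of 12 past that size, and H2-T23 was at 299 and 227 CPM. Both medians lay at or below the lowest 0.01% of random lists. The interferon-stimulated difference was not shared by all clusters: the median was 0.04 in cluster 4 (398 and 977 cells) and -0.14 in cluster 7 (637 and 307 cells), and ran from -0.28 to -1.10 in the other 7. Cluster 7, with Ifit2 among its leading genes, had the highest Isg15 (1739 and 1540 CPM) and Irf7 (840 and 566.5 CPM) of these clusters. It held fewer cells in the library titled Blood, which lowers the summed values there. With the macrophage-like clusters given equal weight in both libraries, an alternative chosen after seeing the data, the interferon-stimulated median was -0.41 with 5 of 22 members at least 1.5-fold lower, and the median for interferon gamma and MHC class II was -0.13.

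Among the genes lowest in macrophage-like cells of the library titled Blood, Retnla, a secreted product of alternatively activated macrophages, was at 126 CPM (123 to 128) and 15.7 CPM (14.9 to 16.6), a log2 ratio of -2.66. Retnla was highest in cluster 14, with 230 and 304 cells, at 4120 and 633 CPM. It was at most 60.6 CPM in any other macrophage-like cluster of either library. When each library was clustered on its own, the log2 ratio of Retnla was -0.90. Ly6c2, a surface marker of inflammatory monocytes, was at 113 and 39.9 CPM, Tmem176b at 106 and 33.1 CPM, Tmem176a at 58.5 and 19.6 CPM, and Ms4a4c at 299 and 141 CPM. Genes of the cell cycle had a median log2 ratio of -0.32 over 24 measured members, of which 0 passed 1.5-fold, and one of -0.17 at equal cluster weights; Ube2c, which drives exit from mitosis, was at 115.3 and 79.6 CPM.

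The genes highest in macrophage-like cells of the library titled Blood included single chemokines, matrix-degrading enzymes and hypoxia genes. Cxcl3, a neutrophil-attracting chemokine, was at 41.6 CPM (40.3 to 43.0) and 162.5 CPM (160 to 165), a ratio of 3.90 (3.76 to 4.05). Ccl24, an eosinophil-attracting chemokine, was at 80.6 and 207 CPM, Ccl8 at 568 and 1063 CPM, and Pf4, a chemokine also stored in platelets, at 1645 and 3023 CPM. The fixed list of inflammatory cytokines and chemokines as a whole had a median log2 ratio of 0.06, inside its random range of -0.06 to 0.07, with 2 of 17 members at least 1.5-fold higher and 0 lower. At equal cluster weights the median was 0.10, above that range. Arg1, which breaks down arginine, was at 1228 and 2110 CPM, a ratio of 1.72 (1.71 to 1.73), and Slc7a2, a transporter of arginine, at 40.6 and 85.1 CPM. Of 13 measured members of the matrix degradation list 5 were at least 1.5-fold higher and 0 lower. The median was 0.33, above all random lists. As fixed, the list also holds Timp1 and Timp2, inhibitors of such enzymes, and the receptor Plaur. The elastase Mmp12 was at 237 and 471 CPM and the collagenase Mmp13 at 94.3 and 161 CPM. Mmp8 (3.80 and 17.9 CPM) is a neutrophil gene, and S100a8 and S100a9 RNA in macrophage-like cells also stood at 12.3 and 74.7 CPM. How much of the Mmp8 difference comes from neutrophil RNA was not tested. Hypoxia and glycolysis genes had a median of 0.20, with 4 of 19 at least 1.5-fold higher, among them Ero1l (63.8 and 118.5 CPM), which oxidises proteins in the endoplasmic reticulum, and Bnip3 (83.2 and 141 CPM), which acts in mitophagy. Cholesterol efflux and lipid genes had a median of 0.17, with 4 of 19 at least 1.5-fold higher, such as the fatty acid binding protein Fabp5 (491 and 807 CPM). At equal cluster weights the log2 ratios of Cxcl3, Mmp12 and Arg1 were 1.15, 0.39 and 0.48 in place of 1.84, 0.98 and 0.78. The hypoxia and lipid medians were then 0.095 and 0.11, with 1 of 19 members at least 1.5-fold higher in each. In the matrix degradation list 2 of 13 members were at least 1.5-fold higher at those weights. Within clusters, Mmp12 was close between the libraries only in cluster 4, where it was highest, at 2504 and 2310 CPM, a log2 ratio of -0.12. In the other macrophage-like clusters its log2 ratio ran from 0.39 in cluster 7 to 1.504 in cluster 6. That of Arg1 was 0.15 in cluster 4 and ran from 0.36 in cluster 1 to 0.96 in cluster 2 among the others. With each library clustered on its own, Cxcl3 was at 0.89 and Mmp12 at 0.62.

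**Figure D2:**
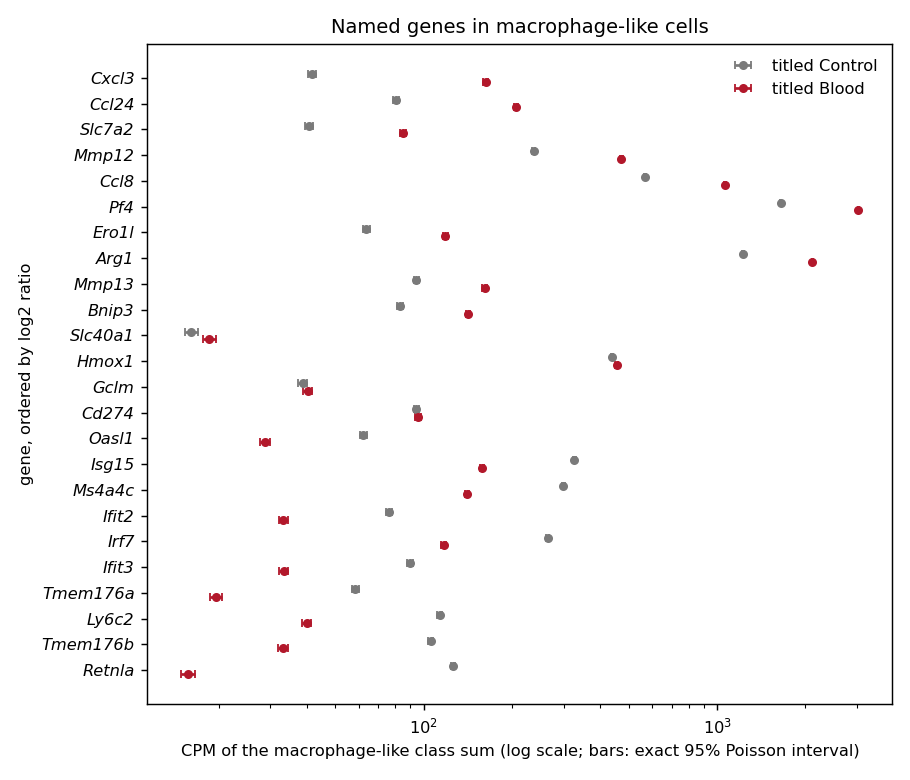
CPM of the macrophage-like class sum (x axis, log scale) for the 10 genes highest and the 10 lowest by log2 ratio and for Hmox1, Slc40a1, Gclm and Cd274 (y axis, ordered by log2 ratio) in the libraries titled Control (grey) and titled Blood (red), with bars for exact 95% Poisson intervals. Retnla sits at 126 and 15.7 CPM, Cxcl3 at 41.6 and 162.5 CPM, and Hmox1 at 437.5 and 454 CPM.

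Genes that handle haem and iron, the load that engulfed erythrocytes bring to a macrophage, were close between the libraries when summed over macrophage-like cells. Hmox1, the enzyme that opens haem, was at 437.5 CPM (433 to 442) and 454 CPM (450 to 459), a ratio of 1.04 (1.02 to 1.05). Within clusters it differed in both directions: in cluster 4, where Hmox1 was highest and which held 398 and 977 cells, it was at 3907 and 2424 CPM, and in cluster 14 at 831 and 1893 CPM. The iron exporter Slc40a1 was at 16.1 and 18.6 CPM, the ferritin chains Fth1 at 12254 and 13189 CPM and Ftl1 at 6961 and 6901 CPM, the haptoglobin-haemoglobin receptor Cd163 at 8.14 and 8.86 CPM, and Spic, a transcription factor of red pulp macrophages, at 2.98 and 2.27 CPM. Of 21 measured iron and haem genes 0 passed 1.5-fold, with a median of 0.05 at percentile 93.4 of random lists. Targets of NRF2, the oxidative stress regulator, also had 0 of 20 members past 1.5-fold, with a median of 0.08 at percentile 99.3; Gclm was at 38.7 and 40.2 CPM, Srxn1 at 28.5 and 28.2 CPM, Txnrd1 at 91.4 and 99.9 CPM, and Gsr, glutathione reductase, at 60.3 and 87.8 CPM. Cd274, which encodes PD-L1, was at 94.3 and 95.7 CPM. The signs of the summed values depended on the setting: with each library clustered on its own the NRF2 median was -0.015 and the Hmox1 log2 ratio -0.33, at equal cluster weights they were -0.010 and -0.38, and with the mean of each cell's own CPM they were 0.18 and 0.65.

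Interferon-stimulated genes were also lower in the library titled Blood in each of the other classes with at least 100 kept cells in both libraries and in mesenchymal-like cells. The median log2 ratio was -0.82 in NK cell-like cells (14 of 20 members at least 1.5-fold lower), -0.64 in T cell-like cells (11 of 20), -0.59 in neutrophil-like cells (10 of 19), -0.57 in mesenchymal-like cells (9 of 20), -0.56 in conventional DC-like cells (9 of 22) and -0.37 in monocyte-like cells (8 of 21), with 0 members at least 1.5-fold higher in any of them. In NK cell-like cells Ifi204, a DNA sensor, was at 63.5 and 25.1 CPM and Usp18, a brake on interferon signalling, at 59.0 and 26.9 CPM. The median was -0.25 in NK cell-like cells with doublets kept, and -0.94 in monocyte-like cells at a Leiden resolution of 2.

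**Figure D3:**
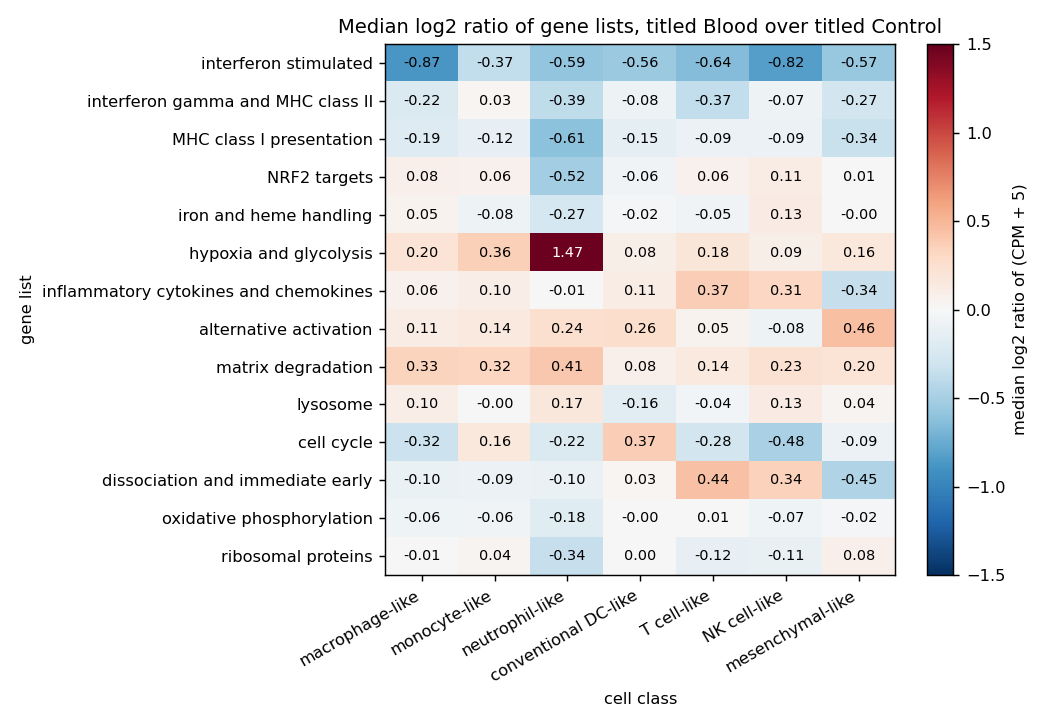
Median log2 ratio of (CPM + 5), titled Blood over titled Control, for gene lists (y axis) in cell classes (x axis), 1 library per group; blue is lower and red higher in the library titled Blood. The interferon-stimulated list is negative in every class drawn, from -0.87 in macrophage-like to -0.37 in monocyte-like cells, and the hypoxia and glycolysis list reaches 1.47 in neutrophil-like cells.

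Neutrophil-like cells of the library titled Blood carried more RNA of hypoxia and glycolysis genes. Of 20 measured members 19 were at least 1.5-fold higher, with a median log2 ratio of 1.47, above all random lists. Bnip3 was at 156 and 743 CPM, Ero1l at 330.4 and 1201 CPM, Mif, a cytokine, at 572 and 2038 CPM, and Ldha, which makes lactate, at 675 and 1585 CPM. Genes of the ATF4 and unfolded protein response had a median of 0.63, with 8 of 16 at least 1.5-fold higher and 2 lower, and the endoplasmic reticulum proteins Hyou1 (7.11 and 57.4 CPM) and Sec61a1 (14.2 and 104 CPM) were among the highest genes, beside Fndc3a (42.6 and 306.5 CPM). NRF2 targets had a median of -0.52, with 8 of 18 at least 1.5-fold lower and 0 higher, such as Gclm (124 and 46.2 CPM) and Txnrd1 (270.0 and 133 CPM), whereas Hmox1 was at 398 and 504 CPM. The lowest genes were the mast cell proteases Cma1 (1133 and 7.80 CPM), Cpa3 (700.0 and 5.31 CPM) and Mcpt4 (469 and 75.5 CPM) and the basophil protease Mcpt8 (359 and 0.936 CPM). They were borne by 4 of 134 and 9 of 1777 cells. Without those cells 260763 and 3180861 UMIs were left and the hypoxia median was 1.38. Over 12 alternative settings the NRF2 median ran from -0.69 to -0.41. The unfolded protein median without those cells is not given here. Mcpt1 had no UMI in the library titled Control, which allows up to 10.7 CPM, and stood at 93.9 CPM in the other. Cluster 5 held 112 of the 134 cells of the library titled Control, whereas clusters 5 and 13 held 1062 and 715 of the 1777 in the other, and the class sums were 281436 and 3204036 UMIs. Equal cluster weights were not applied to this class. How far cluster mix goes with its hypoxia, unfolded protein and NRF2 medians was not tested.

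T cell-like cells of the library titled Blood had lower values of naive and memory genes and, as summed, a higher median of effector genes. The effector and cytotoxic list had a median log2 ratio of 0.44 over 18 members, of which 2 were at least 1.5-fold higher and 1 lower, with interferon gamma (Ifng) at 307 CPM (292 to 324) and 482 CPM (466 to 499) and Tnf at 23.1 and 49.5 CPM. The exhaustion and checkpoint list had a median of 0.39 over 12 members, 1 of them at least 1.5-fold higher, with the inhibitory receptor Havcr2 at 81.3 and 121 CPM. The naive and memory list had a median of -0.59, with 5 of 10 at least 1.5-fold lower, including the chemokine receptor Ccr7 (176 and 81.9 CPM) and the transcription factor Tcf7 (130.3 and 74.0 CPM). The regulatory T cell list had a median of -0.39, with 1 of 13 at least 1.5-fold lower and Ikzf2 at 538 and 378 CPM. The dissociation and immediate early list, which tissue digestion can also raise and which includes heat shock genes, had a median of 0.44. Of its 20 members 5 were at least 1.5-fold higher. Egr1 (121 and 272 CPM) and Csf2 (25.3 and 53.2 CPM) were among the highest genes, and the macrophage and MHC class II transcripts C1qc (99.98 and 46.0 CPM) and H2-Eb1 (126.5 and 52.2 CPM) among the lowest. In the library titled Blood 654 of 1284 T cell-like cells fell in cluster 8, led by Cd8b1 and Cd8a, against 262 of 831 in the library titled Control, where clusters 16, 15 and 11.2 held 213, 209 and 121. With the T cell-like clusters at equal weight, chosen after seeing the data, the effector median was 0.035, inside its random range of -0.06 to 0.08, and the exhaustion (0.059) and regulatory (0.069) medians also lay inside theirs. The naive and memory median was then -0.32, with 1 of 10 members at least 1.5-fold lower. The dissociation and immediate early median was 0.45 and the interferon-stimulated median -0.65.

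In mesenchymal-like cells the lowest genes in the library titled Blood included secreted proteins and a contractile gene. Cxcl14, a chemokine of fibroblasts, was at 154 CPM (144 to 165) and 3.24 CPM (1.62 to 5.79), the acute phase protein Saa3 at 50.4 and 0.589 CPM, the stromelysin Mmp3 at 66.4 and 2.94 CPM, Igfbp7 at 118 and 10.9 CPM, and Tagln, an actin-binding protein of contractile cells, at 108 and 11.5 CPM. Of the pericyte markers Rgs5 had 31 and 0 UMIs and Abcc9 10 and 0 UMIs in the same class, whereas Notch3 had 5 and 11. The keratin Krt14 had 254 and 4 UMIs, but other skin epithelial markers gave little sign of epithelial cells. Krt5, Krt15 and Krt17 had 0 UMIs in both libraries, Epcam 2 and 2, and Dsp 17 and 8. The TGF-beta and myofibroblast list had a median log2 ratio of -0.10, inside its random range of -0.11 to 0.10, with 4 of 15 at least 1.5-fold lower and 0 higher. Extracellular matrix genes had a median log2 ratio of -0.17, with 2 of 20 at least 1.5-fold lower and 0 higher; Tnc, tenascin C, was at 135 and 39.1 CPM. MHC class I presentation genes had a median of -0.34 and interferon gamma and MHC class II genes one of -0.27, with the T cell-attracting chemokine Cxcl9 at 174 and 47.1 CPM. The ATF4 and unfolded protein response list had a median of 0.32, with 3 of 19 at least 1.5-fold higher and 1 lower, including Chac1 (13.5 and 31.2 CPM) and Trib3 (10.1 and 21.5 CPM). Highest were Mmp12 (9.76 and 55.3 CPM), the imprinted RNA H19 (35.3 and 123 CPM), the water channel Aqp1 (28.6 and 75.3 CPM), Pf4 (68.3 and 157 CPM), the retinoic acid binding protein Crabp1 (111 and 242 CPM) and Arg1 (45.3 and 98.9 CPM). Of these Mmp12, Pf4 and Arg1 are macrophage genes, and the macrophage marker Apoe stood at 569 and 1086 CPM in the same cells. Hmox1 was at 88.6 and 75.3 CPM and the NRF2 median was 0.01. The values rest on 103 and 53 cells with a median of 49728 and 59612 UMIs, for which doublets with macrophages stay open, and with the mean of each cell's own CPM the matrix median was 0.028 and the Hmox1 log2 ratio 0.070.

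The named genes that bear most on the comparison lie as follows on GRCm38 in the GENCODE M21 annotation, each a protein-coding gene: Hmox1 (ENSMUSG00000005413) on chromosome 8 from 75093621 to 75100589, Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484, Retnla (ENSMUSG00000061100) on chromosome 16 from 48842551 to 48844461, and Irf7 (ENSMUSG00000025498) on chromosome 7 from 141262706 to 141266481. Pf4 (ENSMUSG00000029373) and Cxcl3 (ENSMUSG00000029379) lie near each other on chromosome 5, from 90772435 to 90773383 and from 90786103 to 90789600. Mmp13 (ENSMUSG00000050578) and Mmp12 (ENSMUSG00000049723) lie side by side on chromosome 9, from 7272514 to 7283331 and from 7344381 to 7369499.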

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

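No explanation was tested for the differences between cell classes given here, and which pair of classes to set side by side was chosen only after the medians were seen. In each case the median of a gene list fixed in advance, as summed over each class, lay above its random range in 1 class and below it in another, and the difference between the classes was itself not tested, since each group has 1 library.

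Cell cycle genes had a median log2 ratio, titled Blood over titled Control, of 0.37 in conventional DC-like cells, with 4 of 24 members at least 1.5-fold higher, and of -0.48 in NK cell-like cells, with 9 of 21 at least 1.5-fold lower, a difference of 0.85. The dissociation and immediate early list joins genes switched on within minutes by stimulation or tissue digestion with heat shock genes. It had a median of 0.44 in T cell-like and -0.45 in mesenchymal-like cells, a difference of 0.89. Inflammatory cytokines and chemokines had a median of 0.37 in T cell-like and -0.34 in mesenchymal-like cells, a difference of 0.72. In the mesenchymal-like class 4 of 15 members were at least 1.5-fold higher and 4 lower, with a mean of -0.06; Cxcl3 was at 1.07 and 22.7 CPM and Ccl2 at 999.6 and 514 CPM. At equal cluster weights the T cell-like median was 0.13. Neutrophil RNA was higher in both classes, with S100a8 and S100a9 at 12 and 442 UMIs in T cell-like and 13 and 62 in mesenchymal-like cells. Neutrophil-like cells of the library titled Blood carry Cxcl3 at 7115 CPM. How much of the Cxcl3 in either class comes from such RNA was not tested. The T cell effector list had a median of 0.44 in T cell-like and -0.62 in neutrophil-like cells, a difference of 1.07. Only 7 of its members were measured in neutrophil-like cells, and the source of their RNA there was not tested. At equal cluster weights the T cell-like effector median was 0.035, inside its random range of -0.06 to 0.08, so the T cell-like side of this difference was not seen there.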

How the results depend on the processing

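The equal cluster weights, the counting of the low-UMI stromal cluster, the removal of neutrophil-like cells with a mast cell marker and all alternatives run on T cell, neutrophil, NK cell, monocyte and conventional DC lists were chosen after seeing the data. Except where noted, the cause of a shift was not tested. The neutrophil-like share ratio ran from 10.2 to 10.7 (4.28 among cells of 5000 UMIs or more), the macrophage-like from 0.804 to 0.855 and the T cell-like from 1.17 to 1.27. The monocyte-like ratio turned to 0.794 and 0.842 at Leiden resolutions of 0.5 and 2, and to 0.733 with each library clustered on its own. The mesenchymal-like ratio was 0.643 with doublets kept, 0.786 with each library on its own, 0.649 with cells titled Control thinned to 71.0% of UMIs and 0.649 with the low-UMI stromal cluster counted. Separate clustering gave log2 values of -0.015 for NRF2 targets, -0.33 for Hmox1 and 0.14 for hypoxia in macrophage-like cells. Equal cluster weights, which remove differences in cluster mix, gave -0.010, -0.38 and 0.095 for these and -0.41 for interferon-stimulated genes; the latter stood at -0.74 at resolution 2 and -0.95 with a pseudocount of 1. In T cell-like cells equal weights gave 0.035 for effector, -0.32 for naive and 0.069 for regulatory genes, and keeping doublets 0.54 for effector genes; it gave 1.21 for neutrophil-like hypoxia. The mean of each cell's own CPM gave 0.18 for macrophage-like NRF2 targets, and 0.028 for matrix genes and 0.070 for Hmox1 in mesenchymal-like cells. Of 310 values for single genes and other lists 50 moved beyond their counting or random-list range, 1 of them, the macrophage-like inflammatory median, to -0.035. At resolution 0.5 no conventional DC-like class formed. No paired analysis was possible because each group has 1 library. Depth limits neutrophil-like values most, at 281436 UMIs titled Control.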

Other observations

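All tests of explanations given here, except that of the neutrophil-like share among cells with at least 2500 UMIs, were chosen only after the result they bear on was seen.

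In monocyte-like cells the library titled Blood had higher levels of genes that were also higher in its macrophage-like cells. Ccl24 was at 80.2 and 634 CPM, Cxcl3 at 47.1 and 309 CPM, Mmp12 at 11.2 and 58.8 CPM and Arg1 at 225 and 569.5 CPM, and Inhba, a subunit of activin A, was at 30.5 and 115.1 CPM. Hypoxia and glycolysis genes had a median log2 ratio of 0.36, with 5 of 19 at least 1.5-fold higher. The matrix degradation list had one of 0.32, with 5 of 12 members at least 1.5-fold higher and 1 lower. The calgranulin S100a8 (813 and 170.5 CPM) and Lcn2, an iron-siderophore binding protein (70.8 and 6.74 CPM), were lower in these cells of the library titled Blood. By contrast, S100a8 and S100a9 RNA in T cell-like cells was higher in that library.

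In NK cell-like cells the granzymes differed in direction: Gzmg was at 471 and 1614 CPM and Gzmf at 1096 and 2646 CPM, whereas Gzmb was at 1605 and 1053 CPM. Ifitm1 (407 and 1122 CPM) and the chemokine Cxcl2 (25.1 and 158 CPM) were higher. S100a8 at 2.83 and 61.1 CPM shows some neutrophil RNA in the same cells, against 22302 CPM in neutrophil-like cells of the library titled Blood. How much of the Ifitm1 and Cxcl2 differences this RNA accounts for was not tested. In conventional DC-like cells Ccl17, which attracts T cells, was at 93.0 and 337 CPM, and the macrophage transcripts C1qa (257 and 78.9 CPM) and Apoe (780.4 and 306 CPM) were lower. In macrophage-like cells the ferroptosis-related list had a median of 0.21 over 8 members (0.13 at equal cluster weights), lysosome genes one of 0.10 over 20 (0.070 to 0.18 over the alternatives), alternative activation genes one of 0.11 with 2 of 15 at least 1.5-fold higher and 1 lower, and oxidative phosphorylation genes one of -0.06 over 16.

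Interferon-stimulated genes were lower in the library titled Blood in each class compared. Giving the macrophage-like clusters equal weight brought their median log2 ratio from -0.87 to -0.41, still outside the central 95% of random lists (-0.04 to 0.06), which argues against cluster mix as the whole cause, although it goes with part of the difference and the clusters were themselves built from genes that include these. RNA of macrophages in T cell-like cells was scaled by C1q transcripts. It accounted for 2.65% of the summed list level there in the library titled Control and 1.35% in the library titled Blood. That level was 4610 CPM titled Control and 2911 CPM titled Blood. These are shares of the level in each library, and the share of the difference was not worked out. Being small beside the difference in level, they argue against free macrophage RNA as the main source of the T cell-like difference. Free RNA of other classes was not tested. With 1 library per group, preparation, animal and treatment cannot be told apart, and with contradictory labels a treatment effect could have either sign.

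The neutrophil-like share was 10.3 times as high in the library titled Blood. Among kept cells with at least 2500 UMIs the ratio was 7.96 (5.20 to 12.7), which argues against the calling of low-UMI barcodes as the whole cause. S100a8 and S100a9 RNA in T cell-like cells was 25.7 times as high (14.6 to 50.2). That RNA cannot show neutrophils lost before loading, and remaining doublets with called neutrophils could raise it along with their share. Neutrophils that burst or went uncalled in the library titled Control therefore stay open as a cause. In NK cell-like cells S100a8 and S100a9 RNA was 17.5 times as high (10.2 to 32.6), and in conventional DC-like cells 49.0 times (24.6 to 114). It was 6.09 times as high (5.71 to 6.51) in macrophage-like and 7.91 times (4.30 to 15.7) in mesenchymal-like cells. The T cell-like and conventional DC-like intervals lie above 10.3, the NK cell-like and mesenchymal-like intervals span it, and only the macrophage-like interval lies below it. The macrophage-like value depended on the gene. S100a8 alone was 4.43 times as high there (4.09 to 4.80) and S100a9 alone 10.1 times (8.96 to 11.3). A partial loss was therefore neither shown nor excluded. The ratio was lower at higher limits, 9.73 at 1000 UMIs and 4.28 (1.18 to 23.4) at 5000 UMIs with 3 and 13 cells, so calling may still account for part. The tissue piece, the animal, an unstated gate and the treatment cannot be told apart with 1 library per group. A larger neutrophil influx in that tumour may be a biological source and was not tested.

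The 10 genes highest in macrophage-like cells of the library titled Blood, led by Cxcl3 and Ccl24, had a median log2 ratio of 0.89 as summed and 0.67 at equal cluster weights, where the 2nd lowest and 2nd highest gene stood at 0.48 and 1.15. Because the genes were picked by their values, 10 were picked again in a random 50% of the cells, 8 of them the same. The other cells come from the same libraries, so this covers counting error in the picking and not selection on a difference between libraries. In those other cells the median of the 10 genes picked again was 0.65 at equal weights, with the 2nd lowest at 0.39. Over the 9 clusters the median of the first 10 ran from 0.54 to 1.19. The values at equal weights and within clusters argue against cluster mix as the whole cause. However, a stricter bound tried earlier, the 2nd lowest gene past 1.5-fold, was not met, and mix may account for part. Free neutrophil RNA, scaled by S100a8 and S100a9, accounted for at most 9.36% of the difference of any of them, reached for Cxcl3, which neutrophil-like cells carry at 7115 CPM. Differences between animals and treatments remain untested.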
